A study of Mus musculus with 6 samples.

How the data were processed

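RNA was sequenced from brachiocephalic arteries of 6 male mice with a C57BL/6 background, 3 wild type (WT) and 3 Col15a1-/- (KO), after 18 weeks of Western diet. The sex comes from the counts: reads of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were present in all 6 libraries. The series design gives 3 animals per group, and its title describes the deletion as specific to smooth muscle cells. Per the labels' protocols, arteries were flash frozen, total RNA was extracted with Trizol, and libraries were made with standard Illumina protocols. The tissue is labelled as lesion and as a mixture of cell types, so each value is an average over cells whose proportions can differ between animals.

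The deposited values were raw read counts per gene, with no normalization by the authors. Per the file headers, they were made with featureCounts 1.4.6-p4 over exons of a UCSC gene annotation for mm9, summed by gene name, and the command set no option for strand, paired reads or multi-mapping reads. Per the submitters' processing notes, CASAVA, STAR (version given as 3.0), Subread and DESeq2 were also used. With these settings a read over exons of more than 1 gene, an antisense partner included, was left out as ambiguous (0.347% to 0.448% of alignments), and reads that align to several places were not counted. Near-identical copies can therefore lose counts. The haemoglobin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 are listed at 0 in every library, and whether this is the reason was not tested. A deposited summary of the counting held the alignment count for each outcome, and 32.6% to 36.9% of alignments were assigned to genes. Coordinates are those of the mm9 annotation in the count table, and the reference genome of another build was not used here.

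The table held 24391 genes. Total counts per library ran from 22223584 to 26982005, so counting error was small next to the spread between animals for all but genes with few counts. The 45S ribosomal RNA gene Rn45s took 2.04% (WT 2) to 10.4% (KO 3) of counts. No replicate pair agreed within sampling noise. Groups and replicate numbers were taken from the sample titles.

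The 2 groups were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, TMM normalization, filterByExpr with its default minimum count of 10), and p-values were adjusted by the Benjamini-Hochberg method over the 15937 genes tested, with a threshold of 0.05. CPM are TMM-scaled counts relative to library size, and standard errors of log2 fold changes were derived from the F statistic. The 27 gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the lists, and beside it with the correlation estimated per list and with fry. The lists covered contractile smooth muscle, interstitial matrix, basement membrane, matrix proteases, macrophages, lymphocytes, thymocytes, neutrophils and mast cells, endothelium, adventitial fibroblasts, chondro-osteogenic genes, cell cycle, inflammatory mediators, interferon-stimulated genes, lipid handling, cholesterol synthesis, TGF-beta signalling, adipocytes, skeletal muscle, cardiac muscle, nerve, epithelium, erythroid cells, immediate early genes, hypoxia and glycolysis, nuclear oxidative phosphorylation genes, and the unfolded protein response. The groups, tests, lists, rule for named genes and other settings to try were set before the data were examined.

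Named genes were Col15a1; up to 12 genes per direction with the largest change among those past the threshold, with a mean of at least 1 CPM, no overlap between the groups and an established name, with open places filled by smallest unadjusted p; up to 4 members per described list with the smallest unadjusted p; and Apoe, Acta2, Myh11, Lgals3 and Cd68. Genes named outside this rule were chosen after their values were seen, and some list members are not reported here by name.

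The edgeR step was tested on simulated counts with the means, depth and spread of these libraries over 15813 genes, each drawn independently. It recovered 55 of 100 genes changed by 4-fold and 2 of 100 changed by 2-fold, each in the right direction, with 5 false calls. Variation that genes share in the real libraries was absent, so these numbers need not hold for the real data. In a second simulation, with each gene again drawn independently, a 20-member list shifted by 1.5-fold had a camera adjusted p of 9.85e-07 with the preset correlation. With the estimated correlation the adjusted p was 0.104, and 0 other simulated lists were called with either. Members of the real lists varied together, with estimated correlations of 0.0603 to 0.963. The simulation therefore does not show how either test performs on the real lists.

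The other settings set in advance were DESeq2-style size factors, upper-quartile scaling and total counts in place of TMM; DESeq2 1.42.0, limma-voom and limma-voom with sample quality weights; no filter or a stricter filter on low counts; each library left out in turn; the replicate number as a block; ribosomal, mitochondrial and haemoglobin genes left out; a threshold of 0.1; and a test against a 1.5-fold change. A further 3 were chosen after seeing the data, because of neuronal transcripts in WT 2 and KO 3: a fit without both libraries, a fit with the nerve list level as a covariate, and a fit with an indicator of these libraries as a covariate.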

Results

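Transcript levels were measured by RNA sequencing in atherosclerotic brachiocephalic arteries of 3 WT and 3 Col15a1-/- (KO) mice fed a Western diet for 18 weeks. Col15a1 encodes the alpha chain of type XV collagen, a collagen of basement membrane zones. Total gene counts were 22223584, 26982005 and 26972541 in WT 1, WT 2 and WT 3, and 23133078, 23332277 and 26228384 in KO 1, KO 2 and KO 3. The comparison asked how the lesion transcriptome of KO mice differed from that of WT mice.

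Col15a1 itself (chromosome 4, 47220884 to 47326037, mm9) was lower in every KO library. Its counts were 12629, 12111 and 12973 in the WT libraries and 4487, 4542 and 2307 in the KO libraries. The level was 494 ± 83.8 CPM in WT and 161 ± 60.6 CPM in KO (SD, n = 3 each), which is 3.07-fold lower in KO (log2 fold change -1.62, SE 0.33). The adjusted p was 0.587 by edgeR's quasi-likelihood test and 0.00224 by DESeq2, so the call depended on the tool; over all alternatives it ran from 0.00224 to 1.00. The counts were summed over all exons of the gene, so they do not separate a remaining transcript of the KO allele from expression in cells without the deletion.

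No gene passed the threshold in edgeR. The genes described next had the smallest unadjusted p among those whose groups did not overlap. Among genes higher in KO, Timp4, an inhibitor of matrix metalloproteinases, was at 3.71 ± 0.63 CPM in WT and 11.7 ± 2.0 CPM in KO. The Wnt ligand gene Wnt2b was at 8.54 ± 1.6 and 19.8 ± 1.3 CPM, and Slc27a2, which encodes a very long-chain acyl-CoA synthetase, was at 3.02 ± 1.2 and 17.0 ± 6.6 CPM. Sucla2, which encodes a subunit of succinyl-CoA synthetase, was at 94.5 ± 8.4 CPM in WT and 161 ± 15 CPM in KO, and the isocitrate dehydrogenase subunit gene Idh3a at 64.9 ± 7.7 and 109 ± 13 CPM. The remaining genes named on this side were Bche, Perm1, Aspg, Tmem143, Letmd1, Npy1r and Gabrq, with log2 fold changes from 0.79 (Letmd1) to 1.52 (Aspg).

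Among genes lower in KO, Gbp2b, a guanylate-binding protein gene, had the largest fold among the 12 named: 29.8 ± 9.2 CPM in WT and 1.65 ± 1.3 CPM in KO (SD, n = 3 each), a log2 fold change of -4.17 (SE 0.68). Coro1a, which encodes an actin-binding protein of leukocytes, was at 108 ± 8.2 CPM in WT and 61.0 ± 4.7 CPM in KO. The fatty acid binding protein gene Fabp5 was at 267 ± 33 and 144 ± 24 CPM. Apoe, which encodes apolipoprotein E, was at 24.9 ± 2.0 and 12.4 ± 2.3 CPM, a low level in all libraries for lesion tissue with macrophages, in which C1qa was at 392 CPM in WT; the labels name no Apoe genotype. Tnfsf15, Susd3, Hist2h2bb, Arl4c, Slc7a7, Neurl3, Pvrl4 and Kif26b completed this side, with log2 fold changes from -0.65 (Slc7a7) to -1.43 (Tnfsf15).

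None of these 24 genes passed in edgeR, where the smallest adjusted p of any gene was 0.587. At an unadjusted p under 0.05 edgeR gave 1275 of 15937 genes, 641 higher and 634 lower in KO. Over all genes tested, 9701 had a positive and 6236 a negative log2 fold change, with a median of 0.068. DESeq2 called 53 genes, 30 higher and 23 lower, including all 24 named above, while limma-voom called 0 with and without sample quality weights. The groups did not overlap for 16.7% of genes (1327 with KO above and 1335 with KO below), against an expected 10% over all orderings. Genes varied together in these libraries, so the share in a single split can lie far from 10%. The share in other splits was not examined. On simulated counts of this depth and spread, edgeR recovered 55 of 100 genes changed by 4-fold and 2 of 100 changed by 2-fold. Simulated genes were drawn independently, without the variation shared in these libraries, so recovery and false calls in the real data can differ.

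**Figure D1:**
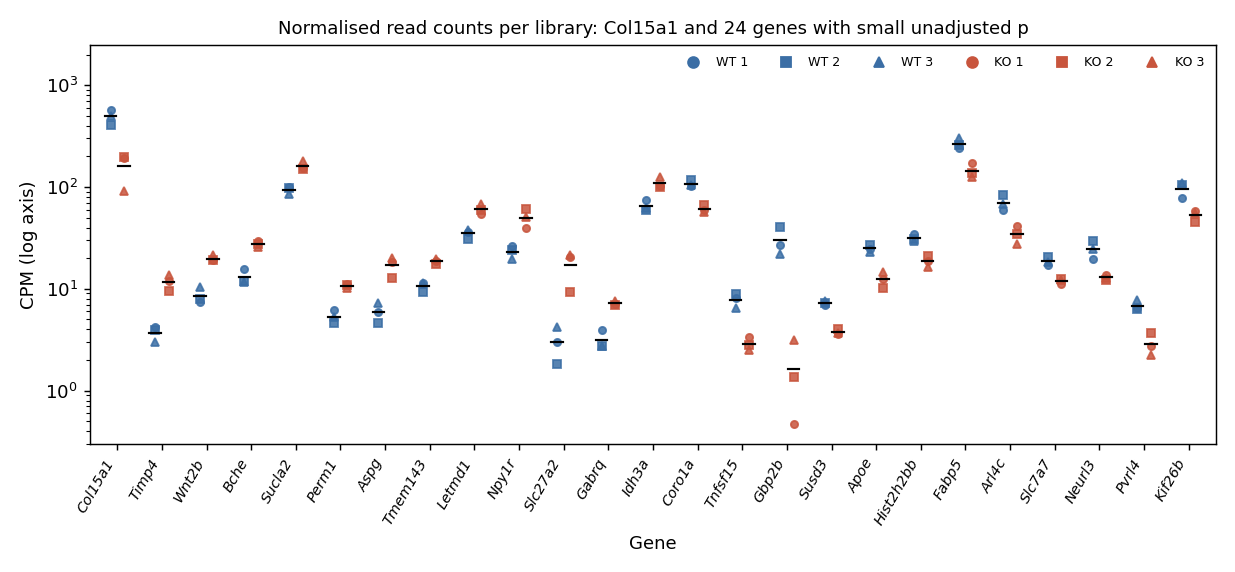
CPM (log axis) of Col15a1 and of 24 genes chosen by small unadjusted p and by separation of the groups, with WT in blue and KO in red, symbols for replicates 1 (circle), 2 (square) and 3 (triangle), and bars for group means. Groups do not overlap because the genes were chosen that way, and none passed in edgeR (smallest adjusted p 0.587).

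Most macrophage transcripts were lower in KO. Of the 22 list members, 20 had a negative log2 fold change, with a median of -0.92, and the mean of the list was lower in each KO library than in any WT library. Aif1, a marker of macrophages, was at 23.97 ± 5.0 CPM in WT and 11.3 ± 2.7 CPM in KO, the integrin gene Itgam at 126 ± 6.5 and 75.0 ± 15.9 CPM, and the complement gene C1qa at 392 ± 30.8 and 208 ± 60.4 CPM. The exceptions, named after their values were seen, were Cd163 (62.3 ± 25 and 123 ± 34 CPM, with each KO library above each WT library, unadjusted p 0.0386, adjusted p 0.612) and Mrc1 (275 ± 75 and 302 ± 88 CPM), both receptor genes of tissue-resident macrophages. Lgals3 was at 471 ± 100 CPM in WT and 214 ± 151 CPM in KO and Cd68 at 156 ± 21 and 82.5 ± 51 CPM, with edgeR adjusted p of 0.717 and 0.704. KO 3 was at 45.2 CPM for Lgals3 and 26.9 CPM for Cd68, while KO 1 was at 337 and 127 CPM and KO 2 at 261 and 93.6 CPM. No member passed over all genes tested in edgeR, while DESeq2 called Aif1, and 6 passed in edgeR adjusted over the list alone (Adgre1, Cd14, Fcgr1, C1qa, Aif1 and Itgam). The smallest edgeR adjusted p over the list alone was 0.0386. Adjustment over a list alone, here and for the lists below, does not correct for the 27 lists. The camera adjusted p was 4.76e-12 with the preset correlation of 0.01, but the adjusted p = 0.694 with an estimated correlation of 0.698. Over all lists the estimated correlations ran from 0.0603 to 0.963, each above the preset value. The preset treats list members as nearly independent, so its small p-values, here and for the lists below, are not evidence of a change by themselves. An adjusted p above the threshold with an estimated correlation is likewise not evidence of no change. Camera with that setting missed a simulated list of 20 independent genes shifted by 1.5-fold (adjusted p 0.104). KO 3, which also had the highest neuronal transcripts, had the lowest macrophage level; the median was -0.61 without KO 3 and -0.62 without WT 2 and KO 3.

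Inflammatory mediators and cell cycle genes had the same direction. All 27 inflammatory mediators were lower, with a median log2 fold change of -0.82; the inflammasome gene Nlrp3 was at 8.45 ± 2.1 CPM in WT and 4.66 ± 0.33 CPM in KO, and the cytokine gene Il1b at 14.7 ± 11 and 3.08 ± 1.9 CPM, with 27.8 CPM in WT 2 (log2 fold change -2.25, and -1.40 without WT 2). Of 30 cell cycle genes, 29 were lower, with a median of -0.52; Bub1b was at 11.1 ± 1.8 and 7.06 ± 0.79 CPM. No member of either list passed, over all genes or adjusted over the list alone. The camera adjusted p was 4.76e-12 and 3.48e-12, and adjusted p = 0.694 with an estimated correlation for both. KO 3 was the lowest library in both lists. The medians were -0.52 and -0.33 without KO 3, and -0.33 and -0.41 without WT 2 and KO 3.

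Interstitial matrix, matrix protease and chondro-osteogenic genes were lower as well, but basement membrane genes were not: 11 of 19 were higher, with a median of 0.063 and a camera adjusted p of 0.569 (0.882 with an estimated correlation). This was close to the background of all genes tested, of which 9701 of 15937 were higher, with a median of 0.068. The basement membrane median was 0.22, with a camera adjusted p of 0.00470, without KO 3, and it turned to -0.050 without WT 2, -0.053 without KO 1 and -0.077 without KO 2. The laminin gene Lama2 was at 258 ± 86 CPM in WT and 407 ± 48 CPM in KO. In the interstitial matrix list 25 of 26 members were lower, with a median of -0.50, among them Tnc (554 ± 9.5 CPM in WT, 248 ± 146 CPM in KO) and Col12a1 (300.5 ± 19.9 and 153 ± 79.3 CPM). In the list of matrix proteases and inhibitors 18 of 22 were lower, with a median of -0.72, including Mmp2 (417 ± 28.9 and 271 ± 71.4 CPM) and Mmp14 (214 ± 14.1 and 116 ± 50.9 CPM), while the inhibitor gene Timp4 was higher and was the only member to pass adjusted over the list alone. In the chondro-osteogenic list 17 of 21 were lower, with a median of -0.45; Prg4, which encodes lubricin and was called by DESeq2 alone, was at 187 ± 17 CPM in WT and 67.2 ± 29 CPM in KO, and Sox9 at 15.2 ± 0.57 and 10.4 ± 2.3 CPM. Adjusted p by camera was 1.48e-08, 3.12e-05 and 0.000106 in this order, and adjusted p = 0.706, 0.706 and 0.694 with an estimated correlation. KO 3 was the lowest library in each of these 3 lists, and for chondro-osteogenic genes the groups overlapped. In the same order the medians were -0.22, -0.40 and -0.19 without KO 3, and -0.32, -0.47 and -0.26 without WT 2 and KO 3. Without KO 2 they were -0.78 for interstitial matrix and -0.69 for chondro-osteogenic genes.

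Lipid handling genes were mixed. Of 20 members, 13 were lower, with a median of -0.44 (-0.27 without KO 3), and Fabp5 and Apoe, at the low level given above and with no genotype in the labels, passed adjusted over the list alone. The camera adjusted p was 0.00565, and adjusted p = 0.706 with an estimated correlation. Neutrophil and mast cell genes (8 of 9 lower, median -0.29), lymphocyte genes (16 of 19 lower, median -0.46), interferon-stimulated genes (17 of 20 lower, median -0.18) and immediate early genes (13 of 17 lower, median -0.15) were called lower with the preset correlation, with adjusted p = 0.694, 0.706, 0.711 and 0.706 with an estimated correlation. Of these 4 lists, Csf3r, the receptor of granulocyte colony-stimulating factor, was the only member to pass adjusted over the list alone (edgeR adjusted p 0.0487). Csf3r was at 21.8 ± 4.9 CPM in WT and 9.90 ± 2.7 CPM in KO. In the neutrophil and mast cell list, 9 of the 15 fixed members were tested. Its mast cell protease genes Cpa3, Cma1, Tpsb2 and Mcpt4 hardly changed, with log2 fold changes of -0.0017, -0.088, -0.11 and 0.097.

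Respiratory chain genes were higher in KO. All 22 nuclear oxidative phosphorylation genes had a positive log2 fold change, with a median of 0.39. Adjusted over the list alone, 7 passed, Uqcrc1, Uqcrc2 and Cyc1 among them, with a smallest edgeR adjusted p of 0.0431. Uqcrc2, a subunit of complex III, was at 87.3 ± 10.05 CPM in WT and 126 ± 9.0 CPM in KO. Adipocyte genes were higher too: all 17 had a positive log2 fold change, with a median of 0.94, but no member passed, over all genes or adjusted over the list alone. Cidea, a lipid droplet protein gene of brown fat, was at 35.3 ± 19 and 88.3 ± 11 CPM. Adjusted p by camera was 1.22e-10 and 5.19e-08, and adjusted p = 0.694 with an estimated correlation for both. In both lists the mean of each KO library lay above that of each WT library. Whether fat taken with the artery contributed to the respiratory chain genes, or to Sucla2 and Idh3a, was not tested. WT 2 had the lowest adipocyte level, with a mean log2 CPM of 4.09 against 5.33 to 6.27 in the other libraries. Without WT 2 and KO 3 the medians were 0.24 for oxidative phosphorylation and 0.59 for adipocyte genes, and without KO 3 alone the first was 0.26.

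Contractile smooth muscle genes were called higher with the preset correlation (19 of 20, median 0.37), but not with an estimated correlation (adjusted p = 0.711), and the groups overlapped. Acta2 was at 2117 ± 700 CPM in WT and 2676 ± 1625 CPM in KO, and Myh11 at 3110 ± 827 and 4113 ± 1653 CPM (SD, n = 3 each), with edgeR adjusted p of 0.912 and 0.861. Skeletal muscle (16 of 16, median 1.21), cardiac muscle (12 of 12, median 0.69), hypoxia and glycolysis (15 of 17, median 0.31) and endothelial genes (13 of 16, median 0.25) were also called higher. Adjusted p = 0.711, 0.706, 0.706 and 0.711 with an estimated correlation for these 4 lists in this order. The skeletal muscle level was highest in KO 1, with a mean log2 CPM of 4.42 against 0.21 to 2.87 in the others.

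Camera called 18 of 27 lists with the preset correlation, 11 lower and 7 higher, and none with an estimated correlation or with fry, whose smallest adjusted p was 0.598. With 3 libraries per group, the absence of calls in those tests does not show that no list changed. The 9 other ways of splitting the same libraries into 3 and 3 gave 14 to 20 calls with the preset correlation, so the number of called lists does not separate the genotypes from other groupings. The calls of 10 lists ended with some library left out. The largest adjusted p by camera was then 0.982 for contractile smooth muscle (without KO 2, median 0.052), 0.648 for lymphocyte (without KO 3, median -0.11), 0.168 for neutrophil and mast cell (without WT 1, median -0.32), 0.994 for endothelial (without WT 2, median 0.033), 0.504 for interferon-stimulated (without WT 2, median 0.025), 0.102 for lipid handling (without WT 3, median -0.45), 0.393 for skeletal muscle (without KO 1, median -0.34), 0.129 for cardiac muscle (without WT 2, median 0.29), 0.660 for immediate early (without KO 3, median 0.050) and 0.471 for hypoxia and glycolysis genes (without KO 3, median 0.11). Basement membrane, TGF-beta signalling, adventitial fibroblast, cholesterol synthesis, unfolded protein response, thymocyte, epithelial, erythroid and nerve genes were not called with all libraries.

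**Figure D2:**
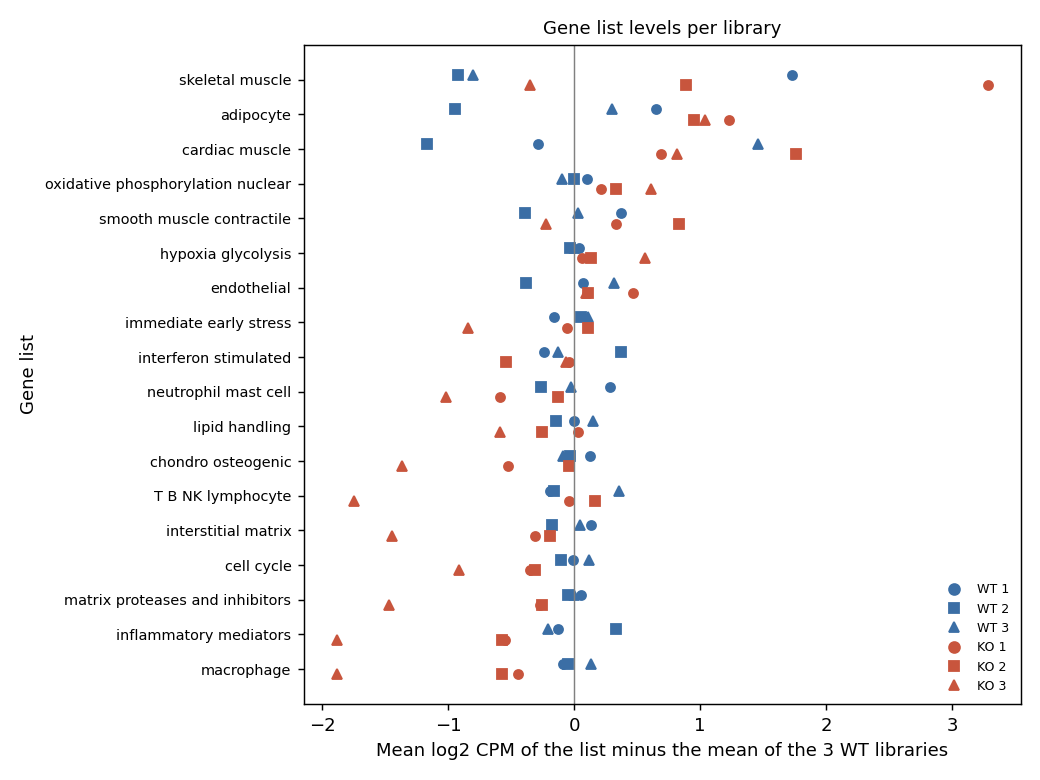
Mean log2 CPM of each of the 18 lists called by camera with the preset correlation, minus the mean of the 3 WT libraries, for WT (blue) and KO (red) with symbols for replicates 1 (circle), 2 (square) and 3 (triangle). Macrophage values lie below all WT values in all 3 KO libraries, with KO 3 lowest. The same holds for the cell cycle, inflammatory mediator, interstitial matrix and matrix protease lists. Oxidative phosphorylation, adipocyte, and hypoxia and glycolysis values lie above all WT values in all 3 KO libraries. No list was called with an estimated correlation.

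WT 2 and KO 3 stood apart from the other libraries. The first principal component held 64.6% of the variance, with scores of 48.4 and 95.0 for WT 2 and KO 3 against -38.6 to -33.7 for the rest. The nerve list had a mean log2 CPM of 5.83 in WT 2 and 6.61 in KO 3 and 3.80 to 4.13 in the others. Th, which encodes the rate-limiting enzyme of catecholamine synthesis, was at 304 CPM in WT 2 and 859 CPM in KO 3 and at 17.8 to 27.3 CPM elsewhere. These libraries were also the ends of the range of the 45S ribosomal RNA gene Rn45s and of Lars2, named after their values were seen, but at opposite ends: 2.04% and 0.154% of counts in WT 2, 10.4% and 3.83% in KO 3, and 6.25% to 9.57% and 2.19% to 2.99% elsewhere. Without both libraries, a choice made after seeing the data, edgeR called 1 gene, Gbp2b (adjusted p 0.0386), and camera called 12 lists, all among the 18.

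**Figure D3:**
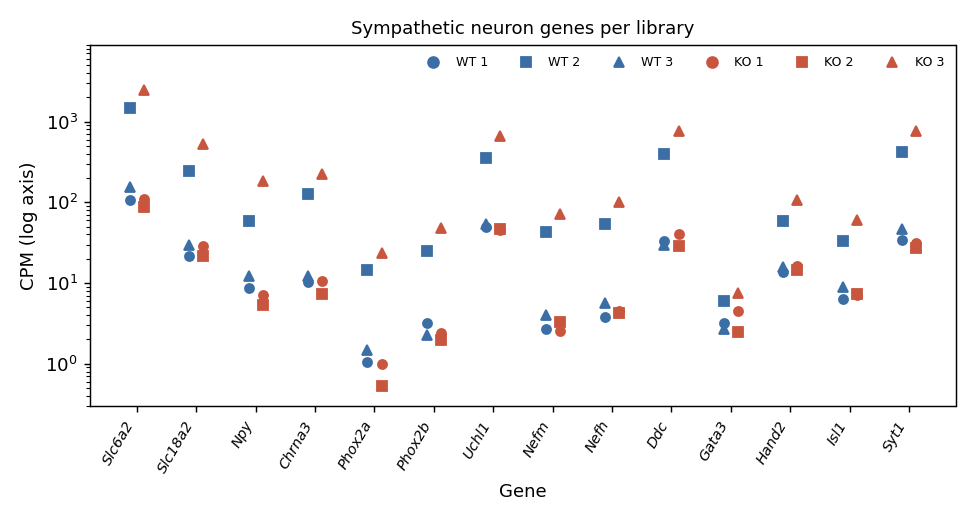
CPM (log axis) of 14 sympathetic neuron genes in WT (blue) and KO (red) libraries, with symbols for replicates 1 (circle), 2 (square) and 3 (triangle). WT 2 and KO 3 lie above the other 4 libraries for each gene.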

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

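The 3 settings that remove or model the neuronal libraries were chosen after the result was seen; the others were planned. The count of genes changed was 0 in edgeR under every scaling and filter, at a threshold of 0.1, against a 1.5-fold change, with each library left out (range 0 to 0) and in limma-voom. It was 53 in DESeq2, with 30 higher and 23 lower. The 3 added settings did not give the same count: 1 gene, lower in KO, without WT 2 and KO 3; 2 genes, both lower, with the nerve list level as a covariate; and 0 with an indicator of the same libraries. Col15a1 passed only in DESeq2 (log2 fold change -1.64, adjusted p 0.00224) and with the nerve list covariate (-1.59, adjusted p 0.0486); it had adjusted p 0.0602 without the 2 libraries and 0.138 with the indicator. Its log2 fold change ran from -1.84 to -1.34 with a library left out. These settings were compared with each other only after the calls were known, so a call in some of them is not evidence beyond the planned fit; the cause of the differences was not tested. The replicate number as a block gave 0 genes and 18 lists, and Col15a1 at the same side of the threshold. Deviations from the group means correlated at 0.43 for replicate 1, -0.68 for replicate 2 and -0.58 for replicate 3. They correlated at 0.77 between WT 2 and KO 3, which stood apart from the rest. These correlations therefore cannot show whether the numbers pair the samples.

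Camera called 18 lists, 13 to 18 with a library left out, and 0 with an estimated correlation and 0 with fry. Macrophage, inflammatory mediator, cell cycle, interstitial matrix, matrix protease, chondro-osteogenic, adipocyte and oxidative phosphorylation lists were called in all 17 settings with the preset correlation. Signs turned for 12 named genes, none past the edgeR threshold, and for 11 lists, of which skeletal muscle, interferon-stimulated and immediate early genes were called with all libraries. Cholesterol synthesis genes were not called with all libraries, but were called in 4 of 17 settings: without WT 2 (median 1.11, adjusted p 0.00574), without KO 1 (0.59, 0.0363), without KO 3 in the other direction (-0.65, 0.0121) and with the indicator (0.17, 0.0236). With an estimated correlation their adjusted p was 0.882. The mean log2 CPM of this list was 5.23 in WT 2 and 5.75 in KO 3, against 3.79 to 3.83 in the other libraries. Leaving out WT 2 or KO 3 alone therefore moved its median in opposite directions. With both left out the median was -0.013 (camera adjusted p 0.744 with the preset correlation). Basement membrane, thymocyte, adventitial fibroblast, TGF-beta, nerve and epithelial lists were also called in some setting but not with all libraries; the cause was not tested. With a library left out, log2 fold changes ran from -0.46 to 2.31 for Dntt, -0.053 to 2.60 for Rag2, -0.014 to 0.65 for Insig1, -0.53 to 1.18 for Tm7sf2, -0.35 to 0.87 for Sc5d, -0.83 to 1.59 for Fdft1, -0.28 to 4.29 for Myh4, -0.34 to 2.34 for Chga, -0.14 to 0.54 for S100b, -2.52 to 3.57 for Th, -2.09 to 0.36 for Slc4a1 and -0.28 to 0.64 for Acta2. List medians ran from -0.077 to 0.22 for basement membrane, -0.46 to 2.31 for thymocyte, -0.093 to 0.47 for adventitial fibroblast, -0.40 to 0.025 for interferon-stimulated, -0.65 to 1.11 for cholesterol synthesis, -0.17 to 0.087 for TGF-beta, -0.34 to 3.06 for skeletal muscle, -0.49 to 1.56 for nerve, -1.82 to 0.36 for erythroid, -0.30 to 0.050 for immediate early and -0.18 to 0.050 for unfolded protein response genes. With quality weights in limma-voom Tm7sf2 was at -0.052 and Th at -0.45. With the nerve list covariate Th was at -0.34, cholesterol synthesis at -0.047 and TGF-beta at 0.024. Without WT 2 and KO 3 Th was at -0.29, cholesterol synthesis at -0.013, TGF-beta at 0.052 and nerve at -0.0081.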

Other observations

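The tests of KO 3 alone, of dilution, of lesion share, of the genotype as the source of neuronal genes and of the interferon response were chosen after the result was seen. The thermogenic fat gene Ucp1, named after its values were seen, was at 80.6 ± 49.6 CPM in WT and 235 ± 48.9 CPM in KO (SD, n = 3 each; edgeR adjusted p 0.591). Apoe was measured at 23.07 to 26.96 CPM in WT and 10.1 to 14.7 CPM in KO libraries; this is low for lesion tissue and the labels name no Apoe genotype, so whether the reads come from an intact allele is not known.

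Neuronal genes were high in WT replicate 2 and KO replicate 3. The 14 genes of a sympathetic neuron list, written after the separation of these libraries was seen and sharing 0 genes with the nerve list, were higher in both libraries than in the other 4, by a median of 3.13 log2 CPM; Slc6a2 was at 1491 and 2456 CPM against 86.8 to 153 CPM. Sympathetic ganglion tissue taken with the artery is a candidate explanation. The pattern was defined by 1 library of each group, so the count of KO libraries above the highest WT library (1 of 3) restates it and tests nothing about the genotype, which stays untested. All 4 other splits that put WT 2 and KO 3 in the same group gave more genes at an unadjusted p under 0.05 (1765 to 2181) than the genotype split (1275), which points to a structure of the samples. The genotype split itself parts WT 2 and KO 3, and the 5 other splits that part them gave 52 to 467.

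Most macrophage genes were lower in KO (20 of 22; Cd163 and Mrc1 were higher). KO 3 alone is argued against: without it the median log2 fold change was -0.61. Dilution of the vessel by outside tissue would lower macrophage and smooth muscle genes alike, if that tissue brought no smooth muscle transcripts of its own. Macrophage minus smooth muscle mean log2 CPM differed by -1.28, KO minus WT (-0.14 ± 0.41 in WT, -1.43 ± 0.46 in KO, SD, n = 3 each). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. This contrast was chosen after macrophage genes were seen to be lower in each KO library, so its separation is partly built in. The difference argues against dilution as the whole cause only if the outside tissue brought no smooth muscle transcripts, which was not tested. The smooth muscle groups also overlapped. More outside tissue in KO as a part of the cause stays open. The adipocyte list mean was higher in each KO library than in any WT library (mean log2 CPM 5.04 in WT and 6.11 in KO). All 16 skeletal muscle genes had a positive log2 fold change, but their groups overlapped. The skeletal muscle direction rested on KO 1, the highest library: without KO 1 the median was -0.34. A smaller share of lesion in the tissue taken remains open: 5 of the 5 other lesion lists also had medians under 0, and with no lesion size analysed here, dissection and genotype cannot be told apart.

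Gbp2b was the gene with the largest decrease among those named. A lower interferon response is argued against as the whole cause of its log2 fold change of -4.17 (SE 0.68), since the other 10 Gbp genes had a median of 0.079 (range -0.24 to 1.02). A small decrease of this response stays open: 17 of 20 interferon-stimulated genes were lower, with a median of -0.18 (camera adjusted p 0.00565 with the preset correlation and 0.711 with an estimated one), but 0.025 without WT 2 (adjusted p 0.504). A chromosome interval of another strain remains open: 1 of 51 tested genes within 5 Mb of Gbp2b had an unadjusted p under 0.01 (1.96%), against 1.39% on other chromosomes (one-sided Fisher's exact p 0.512), too few genes to decide.

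The 10 splits of 6 libraries cannot give a share under 0.1. The genotype split gave 0 genes past the edgeR threshold and the highest other split 0, which no split could fall below, so this count says nothing; for gene lists the genotype split gave 18 and the highest other 20, with 3 splits at 18 or more.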
